A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

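The series holds 3 sequencing libraries from budding yeast (Saccharomyces cerevisiae, strain BY4741 with SKI2 deleted), 1 library per reporter. Per the labels, every strain carried a PGK1 reporter with a stalling sequence, and the 3 sequences were a stem loop, (CGA)12 and (AAA)12. Cells grew in medium without uracil with 2% galactose and 2% raffinose to an optical density near 0.8. Per the labels' protocols, RNA was prepared with hot phenol, an adenylated DNA oligonucleotide was ligated to it, and cDNA was amplified between the adaptor and a primer at position 585 of PGK1, so each read reports 1 RNA 3' end downstream of that primer. Per the submitters' processing notes, cutadapt 1.12, Novoalign, SAMtools 1.13 and bedtools were used. Their settings, the reference sequence and the genome build are not given in the sources used here, nor is any use of molecular identifiers. Reads that began as copies of 1 molecule therefore count separately, and all intervals given cover counting error only.

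Per the file headers, the authors deposited 1 table per library, with a position relative to the ATG, the number of reads and a reading frame. The deposited read numbers are raw counts: they are whole and sum to different totals in the 3 tables. Positions with no read are not listed. The sheet names tie each table to its sample through the sample descriptions. The deposited frame equalled 1 plus the remainder of the position minus 1 on division by 3 in every line that gave both (0 disagreements). The deposited frame therefore follows from the position. Position 1 was taken as the first base of the start codon, which was not checked against a sequence. Frame was missing for 185 positions of the stem-loop table and 13 of the CGA table, and 9 lines of the AAA table held a frame with no position. Frame was recomputed for every listed position. Whether a listed position is the last nucleotide of the RNA or the next one is not given in the sources used here.

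The CGA table also carries 4 cells with no column name, left beside position 958: the authors' deposited number 17819 equals the sum of its reads from position 958 on, followed by that sum as a fraction and as a percent of a total of 7000000, and by the remaining percent. Position 958 was taken as the first nucleotide of the stall in the CGA table on this basis. The stall positions of the other reporters are not given in the sources used here. For the AAA table the same boundary was assumed, and for the stem-loop table the first position after the start of the covered range at 606 with fewer than 10 reads, 1070, was assumed. Both assumptions were made after the data were examined.

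The values computed from these counts were shares of ends with 95% Wilson intervals, the count-weighted median and percentiles of position, shares in 30-nt windows, shares per reading frame, autocorrelation over positions of log2(count + 1), and correlations and total variation distance between libraries. The covered range of a library runs from the first to the last position that holds at least 0.01% of its ends. The region called shared (606 to 957, 352 nt) runs from the first covered position to the one before the CGA boundary. It assumes that the 3 reporters carry the same PGK1 sequence there. The largest frame share was ranked among 10000 shuffles of the positions, and the autocorrelation from 20 to 45 nt among 10000 shuffles of 3-nt blocks. These percentiles describe 1 library each. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

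Profiles were simulated 200 times from the AAA library's 352 covered positions, with their values first put in random order. A 3-fold rise of frame 1 passed the 95th percentile in 200, a 30-nt spacing was recovered in 182, and a 40-nt shift between profiles was recovered in 200. With no effect, 18 profiles passed that percentile for frame and 13 for spacing, both above the nominal rate of 5%. The random order removes the broad shape and the likeness of neighbouring positions, so these rates do not carry over to the real profiles. The 3-fold rise exceeded the real ratios of frame 1 to frame 2 (1.44, 1.53 and 1.43 in the stem-loop, CGA and AAA libraries). The shift past the insert was searched over fewer positions, with fewer ends.

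With 1 library per reporter there was no test between reporters and no p-value. The named positions were chosen by a rule fixed before the data were examined: the 10 positions with the most ends in each library, any of these in more than 1 library, and the fullest 30-nt window. Alternatives were a minimum of 10 ends, removal of the most frequent position or of the first and last 10 covered positions, sums over 3 neighbouring positions, other window sizes, raw or log values, another pseudocount, a running mean over 61 positions, and the shared region alone. Leaving out the first and last 10 covered positions also left out all ends outside the covered range. In the CGA library the last 10 covered positions lay past position 958, and in the AAA library right before it. For spacing, the most frequent position was replaced by the mean of its neighbours. Sums over 3 neighbours did not overlap for shares of ends, but could overlap when shared positions were counted. Intervals for medians, lags and correlations came from 200 Poisson redraws of the counts. The covered range, the shared region, the rule for nearly empty stretches (fewer than 10 ends at 9 or more neighbouring positions) and the values per part of the region were chosen after the data were examined. The locus tag of PGK1 is from the RefSeq gene table of assembly R64, and no genome coordinates are given because the files name no build. Base composition at the ends was planned but not run, because no reporter sequence was used here.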

Results

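RNA 3' ends were mapped along 3 PGK1 reporter mRNAs that differ in a sequence placed to stall ribosomes. PGK1 (locus tag YCR012W) encodes phosphoglycerate kinase, a glycolytic enzyme. Ski2 is the helicase of the Ski complex, which assists the cytoplasmic exosome in 3'-to-5' decay, and the strain lacked it. The stalling sequences were a stem loop, a run of 12 CGA codons (arginine, read by a wobble pair) and a run of 12 AAA codons (lysine). The question named by the series title was where the reporter mRNA is cleaved. The stem-loop library held 4870458 ends at 855 positions, the CGA library 7282449 ends at 683 positions and the AAA library 4154995 ends at 661 positions. There was 1 library per reporter, so each value below stands without a replicate, and its 95% Wilson interval covers counting error only. Positions are relative to the ATG as deposited, and frames and codons take position 1 as the first base of the start codon, which no sequence was used to check.

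The ends began abruptly at position 606 in all 3 libraries, downstream of the primer at position 585. The position before it held 5, 14 and 4 ends in the stem-loop, CGA and AAA libraries, and position 606 held 3665, 7271 and 2025. From there the covered range reached position 1069 in the stem-loop library, 999 in the CGA library and 957 in the AAA library, and held 99.7%, 99.9% and 99.9% of the ends. In the CGA library no position from 964 to 996 held 0.01% of ends, and the range reached 999 only through positions 997 and 999. Its range, and the autocorrelation over it, thus include a nearly empty stretch that the other ranges lack.

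Nearly all listed ends of the codon-repeat libraries lay upstream of position 958. The shares below are of ends that were amplified and mapped. The last listed position was 1293 in the CGA library and 1291 in the AAA library. Whether ends of longer or uncut mRNA were recovered is not known here. In the CGA library 99.755% of ends (interval 99.752 to 99.759) lay before position 958, the boundary used in the authors' deposited table, which gives 99.745% against a rounded total. With the same boundary assumed, the AAA library held 99.871% (99.868 to 99.875) upstream. The position of the stem loop is not known here. Position 1070 is where the ends of that library run out, so the 99.751% (99.746 to 99.755) before it follows from that choice and does not place the stem loop. In the AAA library the ends fell from 13819 at position 957 to 130 at position 958. In the stem-loop library they fell from 583 to 4 at position 1070, which was chosen for that low count. In the CGA library position 957 held 7129 ends and position 958 held 1553. Position 957 was a local peak in all 3 libraries. In the CGA library the position before it held fewer ends than position 958, so these counts show no step there. The CGA ends thinned out over the following 29 nt. Their mean per nt was 5212.5 in the 30 nt before position 958 and 323.6 in the 30 nt from it on. In the AAA library these means were 13842.6 and 15.2. A nearly empty stretch followed in each library, with fewer than 10 ends at every position: 1072 to 1123 in the stem-loop library, 987 to 995 in the CGA library and 966 to 995 in the AAA library. Past it, the mean over 50 nt was 13.8 ends per nt in the stem-loop library, 94.98 in the CGA library and 33.6 in the AAA library. The 50 nt before the boundary had 3165, 14131 and 16976 ends per nt.

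**Figure D1:**
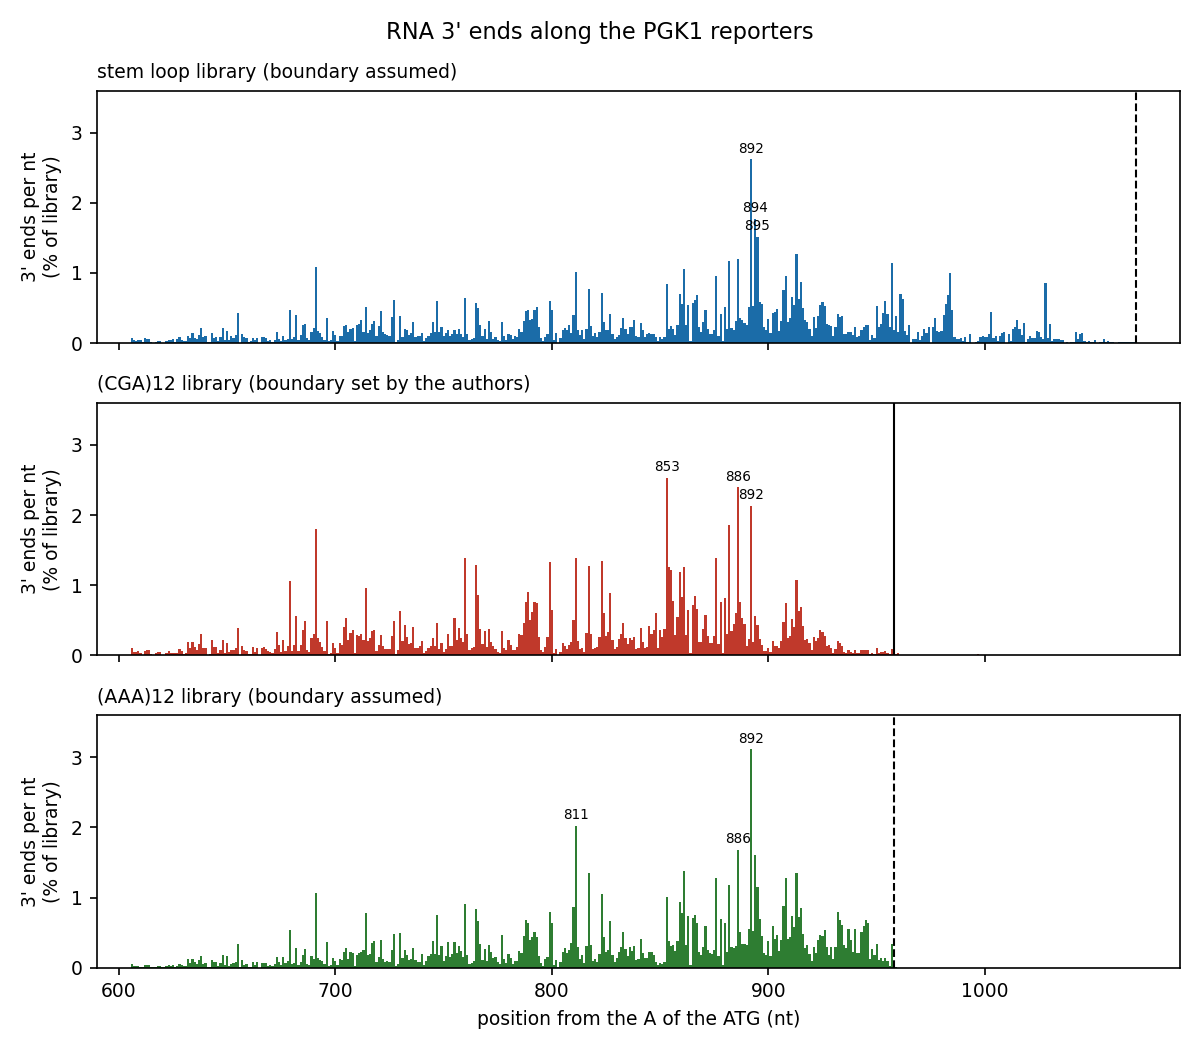
Share of each library's RNA 3' ends (percent per nt, y axis) at each position from the ATG (x axis), for the stem-loop, (CGA)12 and (AAA)12 reporters, 1 library each. The vertical lines mark the stall boundary (solid where the authors' table gives it, dashed where assumed); the 3 highest positions of each library are numbered, and position 892 is among them in all 3.

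The recovered ends were spread widely over the reporter downstream of the primer at position 585. The design does not sample ends upstream of the primer. The medians, percentiles and upstream shares here and in the windows below therefore do not show how many ends lay there. The median end lay at position 824 in the CGA library, 857 in the AAA library and 878 in the stem-loop library, which is 134, 101 and 192 nt upstream of the respective boundary, assumed for the latter libraries. The 10th and 90th percentiles were 691 and 907 in the CGA library, 711 and 928 in the AAA library, and 705 and 981 in the stem-loop library. The 10 nt next to the boundary held 0.527% of ends in the CGA library, 1.73% in the AAA library and 0.125% in the stem-loop library.

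Counted back from the CGA boundary in 30-nt windows, the shares of CGA ends were 2.15% (928 to 957), 9.10% (898 to 927), 17.2% (868 to 897) and 17.2% (838 to 867), with 54.1% further upstream. The same windows held 9.99%, 14.4%, 18.6% and 11.4% of the AAA ends, with 45.5% further upstream. In the stem-loop library the windows counted back from position 1070 held 0.959%, 3.84%, 5.43% and 8.34%, and 81.2% of ends lay further upstream. Counted from the first listed position of each table instead, the fullest 30-nt windows were 888 to 917 in the stem-loop library (18.9%), 848 to 877 in the CGA library (18.6%) and 890 to 919 in the AAA library (20.02%).

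The CGA and AAA libraries, which share the boundary used here, differed most in the window next to it. As a share of the ends in the region from 606 to 957, the window 928 to 957 held 2.15% in the CGA library, 10.01% in the AAA library and 9.56% in the stem-loop library. CGA over AAA was -2.22 on the log2 scale there, and -0.66 in the window 898 to 927. It was 0.59 in the window 838 to 867, and 0.48, 0.80 and 0.53 in the windows 628 to 657, 658 to 687 and 688 to 717. AAA over stem loop ranged from -0.46 (628 to 657) to 0.39 (808 to 837) on the log2 scale, and CGA over stem loop from -2.15 (928 to 957) to 0.73 (838 to 867). In the window 628 to 657 CGA over stem loop was 0.03. These differences exceed the counting error of reads, in which copies of 1 molecule count separately. Whether they exceed the spread between replicate cultures could not be assessed with 1 library each.

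**Figure D2:**
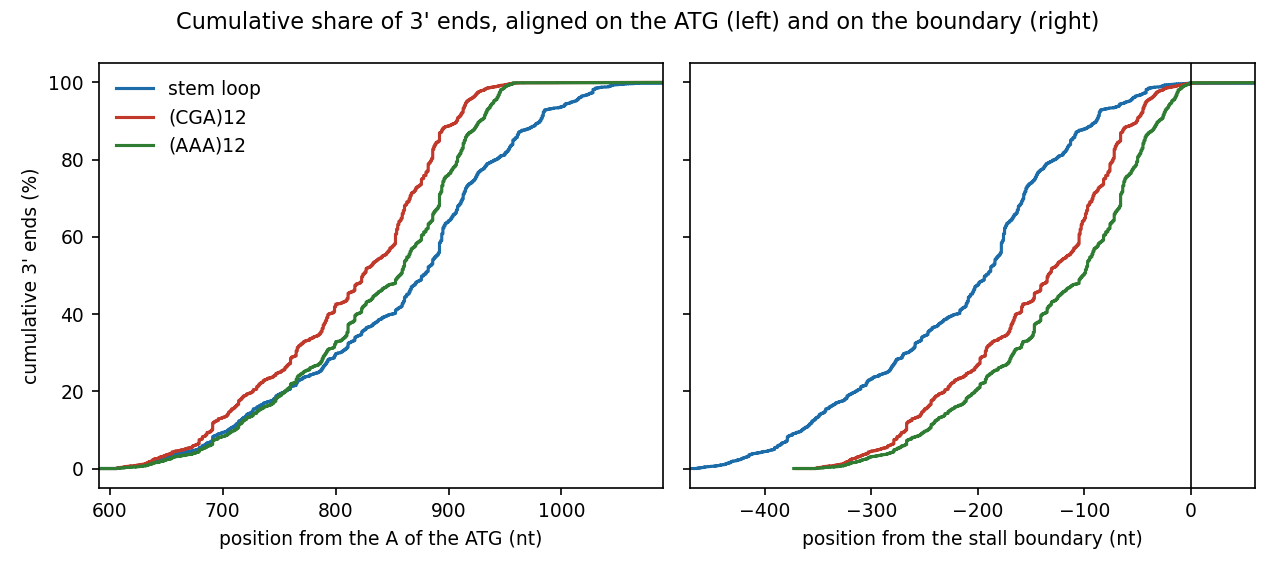
Cumulative share of 3' ends (percent, y axis) against position from the ATG (left x axis) and against position from the stall boundary (right x axis, in nt, boundary at 0), 1 line per library. The CGA line reaches 50% at position 824, the AAA line at 857 and the stem-loop line at 878. The boundary is assumed for the AAA and stem-loop libraries, and for the stem-loop library it is only where the ends run out. Aligned on the boundary, the stem-loop line lies furthest upstream, with its median 192 nt before it, which follows from that choice.

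Within this spread, a small set of positions carried many ends. The 10 most frequent positions held 13.8% of ends in the stem-loop library (13.81 to 13.87), 17.6% in the CGA library (17.54 to 17.59) and 16.2% in the AAA library (16.21 to 16.28). Position 892, in codon 298, was the most frequent in the stem-loop library with 2.62% of ends (2.60 to 2.63) and in the AAA library with 3.12% (3.10 to 3.13), and ranked 3 in the CGA library with 2.13% (2.12 to 2.14). Position 853, in codon 285, led the CGA library with 2.53% (2.52 to 2.55) and held 0.844% and 1.01% of the stem-loop and AAA ends. Position 886 held 1.20%, 2.40% and 1.68% in the stem-loop, CGA and AAA libraries. Position 811 held 1.01%, 1.39% and 2.02%, and position 882 held 1.16%, 1.85% and 1.18%.

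Of the 17 positions among the 10 most frequent of any library, 4 were in all 3 lists (811, 882, 886 and 892), 5 were in 2 lists (691, 861, 876, 894 and 913) and 8 were in 1 list. The stem-loop and AAA lists shared 7 positions, and each shared 5 with the CGA list. With sums over 3 neighbouring positions, stem loop and AAA shared 8, each shared 2 with CGA, and all 3 shared 2. Random draws of 10 from the listed positions would share 0.16 to 0.17. Positions 894 and 895 held 1.77% and 1.52% of the stem-loop ends and 1.60% and 1.15% of the AAA ends, but 0.566% and 0.441% of the CGA ends. Position 957, the last before the codon-repeat boundary, held 1.15% of the stem-loop ends, 0.333% of the AAA ends and 0.0979% of the CGA ends. Positions found only in the CGA list were 760 (1.39%), 799 (1.33%), 823 (1.34%) and 853. Those found only in the AAA list were 817 (1.35%) and 908 (1.28%).

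The profiles were similar as wholes. Across positions listed in both tables, Pearson's r and Spearman's rho were 0.89 and 0.82 for stem loop with AAA, 0.84 and 0.93 for CGA with AAA, and 0.73 and 0.82 for stem loop with CGA. These are the 3 pairs of libraries, computed over 606, 644 and 629 positions, which are not independent replicates, so no p-value was computed. Over these positions the order of the pairs depends on the scale: on log2(count + 1), r was 0.96 for CGA with AAA, 0.81 for stem loop with CGA and 0.79 for stem loop with AAA. These positions include those from 958 on, where the codon-repeat libraries held few ends. In the region from 606 to 957, r was 0.92 for stem loop with AAA, 0.80 for CGA with AAA and 0.74 for stem loop with CGA. Spearman's rho there was 0.93, 0.79 and 0.78 in the same order. For these pairs in this order r was 0.94, 0.83 and 0.83 on log2(count + 1), and 0.91, 0.88 and 0.89 with a running mean subtracted from it. In the last 60 nt of this region (898 to 957), log2 r was lowest for stem loop with AAA (0.55), against 0.79 for stem loop with CGA and 0.72 for CGA with AAA. The share of ends that would have to move to make both profiles equal from 606 to 957 was 12.6% for stem loop with AAA, 21.6% for CGA with AAA and 23.7% for stem loop with CGA.

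The ends were unequally divided among reading frames. Frame 1, taken as the first nucleotide of a codon, held 40.03% of the stem-loop ends (39.99 to 40.07), 42.1% of the CGA ends (42.08 to 42.15) and 40.7% of the AAA ends (40.67 to 40.76). Frame 2 held 27.8%, 27.5% and 28.4%, and frame 3 held 32.2%, 30.4% and 30.9%. Within the covered range the frame 1 share lay at the 97.9th, 98.8th and 97.5th percentile of the largest share in 10000 shuffles, whose medians were 35.9%, 36.5% and 36.2%. Among the 10 most frequent positions, 6 of the stem-loop, 8 of the CGA and 5 of the AAA list were in frame 1. The libraries share many of their frequent positions, so these 3 percentiles are not independent. Counted once each regardless of their ends, 32.9%, 33.4% and 33.6% of listed positions were in frame 1. Nearly every position of the covered range was listed, so near-equal shares follow by construction and do not bear on a frame preference.

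**Figure D3:**
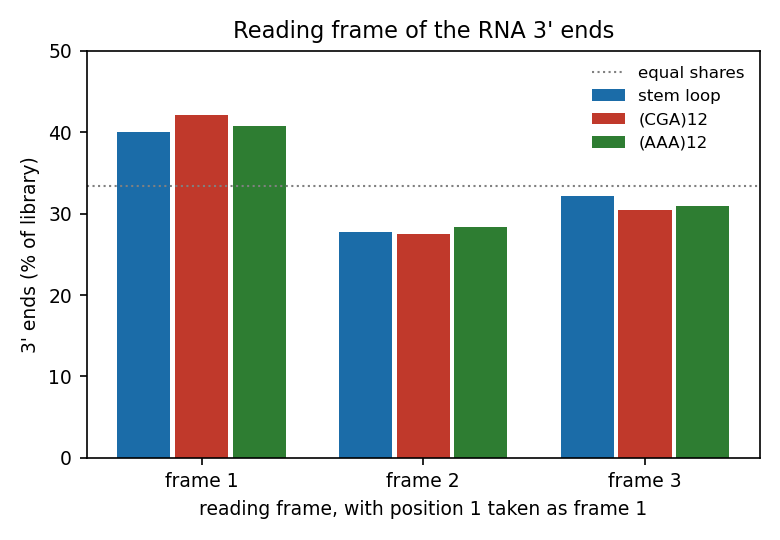
Share of each library's 3' ends (percent, y axis from 0) in reading frames 1, 2 and 3, where frame 1 is taken as the first nucleotide of a codon (x axis); bars are the stem-loop, (CGA)12 and (AAA)12 libraries, 1 each, and the dotted line marks equal shares. Frame 1 was the largest in each library, from 40.03% to 42.1%.

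Spacing was examined because a ribosome covers close to 30 nt. The autocorrelation of log2(count + 1) between 20 and 45 nt was highest at 21 nt in the stem-loop library (0.31) and at the shortest lag, 20 nt, in the CGA library (0.43) and the AAA library (0.38). These values lay at the 100th, 99.99th and 100th percentile of 10000 shuffles of 3-nt blocks, which do not keep the broad shape of a profile. They lay at or next to the lower end of the lags searched. The autocorrelation was higher at 10 nt (0.33, 0.60 and 0.42) and lower at 30 nt (0.26, 0.27 and 0.31). In the AAA library a small local rise went from 0.30 at 28 nt to 0.33 at 34 nt, still below the value at 20 nt. With a running mean over 61 positions subtracted, the highest values were 0.07 at 45 nt, 0.07 at 39 nt and 0.10 at 41 nt, at the 23.0th, 17.0th and 47.2th percentile of 10000 shuffles.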

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

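A few ends were listed upstream of the primer position, a part of the reporter that no comparison addresses: 62 ends at 30 positions in the stem-loop library, 22 ends at 13 positions in the CGA library and 15 ends at 12 positions in the AAA library. Each total is above the 3 counts that a count of 0 allows. By the protocol, reads report ends downstream of the primer, so these listings are not evidence of RNA ends there. How they arose was not examined. No position there held more than 7 ends in the stem-loop library, 5 in the CGA library and 2 in the AAA library.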

How the results depend on the processing

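Of 196 alternative values, 76 stayed within the counting interval of the value reported or within 1.5 times the reported count, 119 moved outside it and 1 changed sign. With 4154995 to 7282449 ends per library these intervals are narrow, so small moves fall outside them too. Requiring 10 ends left 45 of 51 values within it. The cause of each move was not tested unless its construction shows it. The alternatives restricted to the shared region, the assumed boundaries and the ratio to the stem-loop library were chosen after seeing the data. The alternatives for the named positions and for the log2 ratios in the last window of the shared region were not planned either. No paired analysis was possible because there was 1 library per reporter, which also left no replicate to omit, and base composition with its 3 alternatives was not run. The single library per reporter limits these values. Whether depth also does is not known, because copies of 1 molecule count separately (a count of 0 allows 3 counts). Values are given in the order stem loop, CGA, AAA. The most frequent position held 2.64%, 2.55% and 3.18% without the first and last 10 covered positions, and 4.92%, 5.01% and 5.24% as a sum over 3 neighbours. The 10 most frequent held 13.95%, 17.68% and 16.60%, and 24.3%, 29.8% and 28.2%, in the same settings; in the shared region they held 16.28% and 17.61% for stem loop and CGA. The median became 875, 823 and 853 without the most frequent position, 854 for AAA without the edges, and 859 and 856 for stem loop and AAA in the shared region. The upstream share became 99.759%, 99.764% and 99.885% with at least 10 ends, 99.744%, 99.749% and 99.867% without the most frequent position, and 100%, 99.866% and 100% without the edges, a setting that drops all ends past the covered range and so fixes the stem loop and AAA values. With the boundary at the first position under 10 ends from 606 on it was 99.889% and 99.880% for CGA and AAA. The window before the boundary, which for stem loop is only where its ends run out, held 0.588%, 1.55% and 8.30% at 25 nt and 1.08%, 3.51% and 12.1% at 35 nt. The largest frame share, frame 1 throughout when weighted by ends, became 38.4%, 40.6% and 38.8% without the most frequent position, 40.10%, 42.18% and 41.04% without the edges, and 40.71% for stem loop in the shared region. With each position counted once it was 33.7%, 33.5% and 33.6%, near-equal by construction because nearly every covered position is listed. The lag of highest autocorrelation became 45, 39 and 41 nt with a running mean subtracted, 33 and 21 nt for CGA and AAA on raw values, and 27 and 30 nt for their ratio to stem loop. Pearson's r, in the order stem loop with CGA, stem loop with AAA and CGA with AAA, became 0.716, 0.867 and 0.848 without the most frequent positions, 0.689, 0.944 and 0.795 without the edges, 0.697, 0.867 and 0.820 as sums over 3 neighbours, 0.814, 0.791 and 0.963 on the log2 scale, 0.708, 0.904 and 0.826 with at least 10 ends, 0.735, 0.920 and 0.798 in the shared region, and 0.891, 0.913 and 0.883 there with a running mean subtracted from log2. On the log2 scale over all positions in both tables CGA with AAA, not stem loop with AAA, was the most similar pair; in the shared region it was stem loop with AAA (0.941 against 0.832). Shared positions among the most frequent, for the same pairs and then all 3 libraries, became 2, 3, 2 and 2 of the top 5, and 12, 17, 14 and 12 of the top 20. With sums over 3 neighbours they became 2 for stem loop with CGA, 8 for stem loop with AAA, 2 for CGA with AAA and 2 for all 3. The log2 ratio of AAA to stem loop in the last window of the shared region was 0.07 at 30 nt and turned to -0.02 at 35 nt (-0.0154).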

Other observations

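The stem-loop library was the only one to cover positions 958 to 1069 at depth, with 14.7% of its ends. Its most frequent positions there, listed after their values were seen, were 984 in codon 328 (1.01% of ends), 1028 in codon 343 (0.858%) and 961 in codon 321 (0.696%). The frame 1 share was 36.3% in this stretch, with 35.5% in frame 2, at the 17.4th percentile of shuffles. In the same library it was 43.3% from 606 to 781 (98.6th percentile) and 39.6% from 782 to 957 (87.7th percentile). In the CGA and AAA libraries it lay between 40.7% and 42.6% in these parts, at the 90.4th to 94.0th percentile. Just past the nearly empty stretch, the CGA library had 1508 ends at position 997 and 794 at position 999, where the AAA library had 1 and 10.

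The tests of alignment and of the shift past the insert were set before their results were seen; all other tests in this part were chosen afterwards. The first pattern is that positions with many ends were shared by the reporters although their ends ran out at different positions. With local trends removed, the CGA and AAA profiles correlated with the stem-loop profile at 0.88 and 0.91 when aligned on the ATG, the highest of 251 shifts. Aligned on the boundaries, which are 112 nt apart as assumed, the correlations were -0.10 and -0.07, so the smaller difference was 0.987; this argues against the distance to the stall as what sets single positions only if the stem loop lies elsewhere than the codon repeats, which is not known here. Reads carried over from the AAA library in large number would make the stem-loop profile drop at position 958, but its mean over the next 30 nt was 0.977 of that before. The CGA library held only 2.15% of its ends in the 30 nt before that position, against 9.99% in the AAA library. Reads from the CGA library would therefore cause little drop, and the test cannot exclude them, nor a small part from the AAA library. A preference tied to the sequence and common to the libraries is a candidate explanation (lower correlation 0.885); whether it lies in cleavage, trimming, ligation or amplification stays open, because no library without a stall was analysed here.

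The second pattern is that ends lay further upstream in the CGA library than in the AAA library. An upper size limit in the CGA library was predicted to hold longer amplicons at or below the ratio of CGA to AAA shares before the boundary (0.215). From position 1000 to 1025 that ratio was 0.993 (exact 95% interval 0.894 to 1.10), above the predicted bound. The interval treats reads as independent. In both libraries the same single position held far more ends than any other in this range, and it was kept. The ratio therefore leans on that position, and its value without it was not computed. The 4 positions from 996 to 999, with 2593 CGA and 26 AAA ends, were left out after they were seen to raise the ratio to 3.47. All ends from 996 on made up 0.111% of the CGA library and 0.118% of the AAA library. The test cannot exclude a size limit, because the ratio that would be found past the insert without one is not known. A smooth bias by amplicon length as the whole cause is argued against by steps in the ratio of CGA to AAA shares. From 837 to 846 and 847 to 856 its mean log2 value rose by 1.85 (7.85 standard errors of the spread over positions, the largest rise of 333 places). From 880 to 889 and 890 to 899 it fell by 1.92. The standard errors treat neighbouring positions as independent, and the place was picked as the largest rise. Neighbours were alike in the log2 ratios to the stem-loop library (autocorrelation at 1 nt 0.87 for CGA and 0.76 for AAA), so the 7.85 is likely too high. An earlier test in 30-nt windows, which average over such steps, gave a largest departure of 2.02 SD, past the 2 SD first set as its bound but not the 3 SD to which that bound was raised after the value was known. A size limit, a part played by a smooth length bias, a difference between single libraries and a difference between the stalling codons stay open, with 1 library per reporter.

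The third pattern is the nearly empty stretch past the boundary. If the repeats begin at position 958, as the authors' table may show for CGA, they cover 36 nt up to 993. The mean per nt there, over that of the 50 nt after the stretch, was 2.84 in the CGA library (9710 ends) and 0.377 in the AAA library (456 ends). Most of these ends, 7320 and 391, lay at the 6 positions next to the boundary, and without them the ratios were 0.839 and 0.0644, so whether ends inside the repeats were recovered stays open while the first position of each repeat is not settled. A loss inside the insert alone does not account for the low numbers after it, where the mean was at most 0.00672 of that before the boundary.

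It was also predicted that ends past the insert in the CGA table would follow the stem-loop table from position 958 on, at a shift of 36 to 45 nt. The highest correlation, 0.49, came at 15 nt instead (0.35 at 6 nt for the AAA table), so this gave no estimate of the insert's length. The CGA and AAA tables followed each other best at a shift of 0 there (0.54).

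Spacing was also computed after division by the stem-loop profile, a choice made after the data were examined. The log2 ratio to the stem-loop library had its highest autocorrelation at 27 nt for the CGA library (0.32) and at 30 nt for the AAA library (0.23), at the 99.96th and 99.3th percentile of block shuffles. These ratios are smooth (autocorrelation at 1 nt 0.87 and 0.76), which the shuffles do not keep, so these percentiles are too high. With a running mean subtracted both were highest at 30 nt, at 0.18 and 0.10, the 94.6th and 45.8th percentile, so a spacing was not established.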
